A study of Mus musculus with 16 samples.

How the data were processed

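Gene expression was measured by RNA-seq in 16 samples of mouse bone marrow, MSC and MC38 tumor from WT mice and mice labelled KLF K74R. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with the KAPA mRNA HyperPrep kit, which selects polyadenylated RNA. The deposited table holds raw counts per gene for the 16 libraries, whole numbers that sum to between 14067259 and 18923751 per library, with 1 column per sample. Per the submitters' processing notes, the tools were FastQC, MultiQC, Trimmomatic 0.38 for trimming, HISAT2 2.1.0 for alignment and featureCounts 1.6.0 for counting, on genome build GRCm38. The annotation release used for counting, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Without the strand setting, reads of antisense or overlapping genes cannot be told apart, and values of genes with near-identical copies (immunoglobulin segments, guanylate-binding proteins, ribosomal protein pseudogenes, eosinophil ribonucleases) are uncertain. The column names of the WT tumors carry the letter R, the K74R tumor columns do not, and its meaning is not given in the sources used here. The names of the WT MSC columns hold the letters KCF where those of the K74R MSC columns hold KLF. The meaning of this difference is not given either.

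Samples were grouped by the genotype and tissue in their labels. Gene identifiers were matched to GENCODE release M21 on GRCm38, and all 55536 identifiers in the table had a match, 55450 of them with a transcript length and GC content. Values are given as CPM, counts scaled to a fixed total, computed on the library total times its trimmed mean of M-values factor, with the mean and SD over the libraries of a group. Shares of counts are over the total count of a library. Floors are 3 counts and cover counting error only, since reads without molecular identifiers are not independent molecules.

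Each tissue was tested alone, K74R against WT, with R 4.3.3 and edgeR 4.0.16: genes were kept with filterByExpr by group, libraries were scaled by trimmed mean of M-values, and the quasi-likelihood test (glmQLFit, glmQLFTest) was applied with Benjamini-Hochberg adjustment and a threshold of 0.05. A standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. Fold changes carry edgeR's prior count of 0.125. Differences of the genotype effect between tissues were interaction contrasts in a model of all 16 libraries in 6 groups. Overlaps between tissues were tested with Fisher's exact test, one-sided, with Benjamini-Hochberg adjustment over 12 tests, and, after the result was seen, over the 8 with genes in both lists. Tissues share no library, and whether they share mice is not stated.

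Gene lists for blood, immune, stromal, tumor and skin cell types and for cell states were written down with the design. They named 698 members, of which 695 matched the annotation. A list with at least 5 members after the filter was tested with camera from limma 3.58.1, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists of a tissue, and again with an estimated correlation and with fry. A list's median is over the log2 fold changes of its members tested. Adjusted p-values of camera depend on the preset correlation, and where a list call is given its value with the estimated correlation stands beside it.

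The genes named for a tissue passed the threshold, had an average log2 CPM of at least 0 and had no overlap between the libraries of the genotypes. Gene models without a proper name were left out, and the 10 with the largest log2 fold change in each direction were taken. From each list up to 2 risen and 2 fallen members with the smallest p were added, or, where none passed, up to 2 members with the smallest p, given as values. Klf1, Pdcd1 and Cd274 were named in every tissue, the 5 genes with the smallest p for each interaction, and genes changed in all 3 tissues. Some of the genes that this rule took are not reported here. Members of small counts outside this rule are named where the text says that they were chosen after their values were seen, as are other members given without a value beside a list's count. The sample groups, tests, gene lists, naming rule and alternatives, except those given as added later, were fixed before the data were examined.

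Alternatives were other scalings (relative log expression factors, upper quartile, library size alone), no filter on low counts (a total of at least 1), a filter of at least 1 CPM, DESeq2 1.42.0, limma-voom, robust dispersion, all 16 libraries in a single model, the replicate number as a block, each library left out in turn, and globin, mitochondrial and sex-linked genes removed. For lists they were the estimated correlation, fry, the block and relative log expression factors, and for overlaps adjusted p thresholds of 0.1 and 0.01. Offsets that remove each library's trend on transcript length and GC content, these offsets with the block, a crossed block in MSC, and the removal of gene models that track ribosomal RNA were added after the data were seen. A model was taken to track ribosomal RNA where the SD of its log2 ratio to the annotated ribosomal RNA model over the bone marrow libraries was under 0.3, a limit set after those SDs had been seen.

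The test was checked on simulated counts, with 200 genes changed by 1.5-fold, 2-fold or 4-fold. Each gene was drawn independently, from its mean, the trend of dispersion on level and the library sizes of the comparison. In bone marrow 49.3, 61.2 and 92.4% of the changed genes were called and 7.53% of the calls were false. In MSC 1.49, 10.5 and 77.3% were called, with 1.67% false, and in tumors 44.8, 70.2 and 90.9%, with 6.16% false. In MSC, with 2 libraries per genotype, changes of 2-fold or less were thus mostly below detection. No simulated list without a change was called. Since the simulated genes were independent, this does not measure false calls of lists whose genes vary together. In the data the estimated correlation was 0.917 for the endothelial list in MSC. A list raised 1.5-fold, the B cell list, was called with the preset correlation in each tissue, and with an estimated correlation in bone marrow (27 members, adjusted p = 5.1e-04) but not in MSC (7 members, 0.821) or tumors (13 members, 0.0573). In the data the estimated correlation of this list in bone marrow was 0.597, so the call of independent simulated genes there does not carry over. A loss with the estimated correlation thus does not show, in any tissue, that a list was unchanged.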

Results

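RNA was sequenced from bone marrow, from samples labelled MSC and from tumors of mice with a K74R change in a KLF gene and of wild-type (WT) mice. K74R is a missense allele, with arginine in place of lysine, and the labels name the gene only as KLF. The question stated for the series is how expression differs between the genotypes in each of these tissues. Bone marrow and tumor had 3 WT and 3 K74R libraries each, and MSC had 2 and 2. The tumors grew from MC38, a mouse colon adenocarcinoma cell line, and were taken at a volume of at most 1000 mm3. The genotype label is that of the mouse, and MC38 cells come from a line, so tumor counts mix transcripts of both. The labels leave the abbreviation MSC unexpanded and call the mutant samples KO in their titles and K74R in the genotype field. Nothing in the labels says that replicates were separate mice or cultures, so p-values measure only the spread between these samples, which may be technical.

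Total counts were 15858275, 15552890 and 14079626 in the WT bone marrow libraries and 15292866, 14909550 and 14067259 in the K74R ones. The MSC libraries held 17104435 and 15965993 counts in WT and 18726078 and 16504489 in K74R. The tumor libraries held 18344397, 18923751 and 16817282 counts in WT and 18531555, 15923437 and 16966187 in K74R. At these depths 3 counts in a single library correspond to between 0.159 and 0.213 CPM (counts scaled to a fixed library total), the upper limit that a count of 0 allows, counting error alone. The most abundant transcript was the beta-globin gene Hbb-bs in bone marrow and the mitochondrial mt-Co1 in tumors. Replicates differed by more than sampling noise in every group, so none was taken for a library deposited more than once.

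Klf1, which encodes an erythroid transcription factor and is the KLF gene for which a K74R allele is known from the literature, was examined first. The gene (ENSMUSG00000054191) lies on the plus strand of chromosome 8, positions 84901928 to 84905291 of GRCm38. In bone marrow Klf1 stood at 122.8, 102.1 and 136.3 CPM in the WT libraries and at 129.8, 99.9 and 85.7 CPM in the K74R libraries. The means were 120.4 ± 17.2 and 105.1 ± 22.5 CPM (SD, n = 3 and 3), a difference within the spread of the replicates. In MSC both WT libraries had 0 counts of Klf1, which allows up to 0.0902 CPM over the group, and the K74R libraries had 0.120 and 0.164 CPM, from 5 counts. In tumors Klf1 stood at 0.708, 0.527 and 0.723 CPM in WT and at 0.267, 0.626 and 0.538 CPM in K74R. The log2 fold change of Klf1 (K74R over WT throughout) was -0.20 in bone marrow and -0.46 in tumors, with adjusted p = 0.541 and 0.702 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. A missense allele need not change the level of its transcript, so these values do not check the genotype labels.

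Among the KLF family, which includes regulators of proliferation and differentiation in many cell types, 15 members were tested in bone marrow and 14 each in MSC and tumors. Klf10, a gene induced early by transforming growth factor beta, fell in K74R bone marrow from 49.7 ± 5.96 to 33.7 ± 0.998 CPM (log2 fold change -0.56, SE 0.10, adjusted p = 0.0454 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and no KLF gene rose. Klf10 passed in 12 of 20 alternatives. Its adjusted p was 0.0592 with limma-voom, 0.120 with all 16 libraries in a single model, 0.0511 with length and GC offsets. It was 0.118 and 0.196 without WT library 1 or 3, and 0.0588, 0.219 and 0.212 without K74R library 1, 2 or 3. The family as a whole was not displaced in bone marrow (camera adjusted p = 0.781), and its median was 0.13, its mean 0.03 and its camera direction down. In MSC 0 of 14 members passed over all genes with edgeR, although 7 had an unadjusted p under 0.05 (4 higher and 3 lower). DESeq2 called 1 there and limma-voom 0. Klf8 had a log2 fold change of 1.15 and Klf13 of -0.79 (adjusted p = 0.0903 and 0.0981). Cd274, which encodes the checkpoint ligand PD-L1, had 10.7 ± 0.328 CPM in WT and 7.77 ± 0.792 CPM in K74R bone marrow (adjusted p = 0.163), and its adjusted p was 0.786 in MSC and 0.946 in tumors. Pdcd1, which encodes the receptor PD-1, had 3.18 ± 0.443 CPM in WT and 2.84 ± 1.47 CPM in K74R tumors (adjusted p = 0.894). It had 0 counts in all MSC libraries, and means of 0.397 CPM in WT and 0.717 CPM in K74R bone marrow, too low for the filter on low counts.

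Among the genes that the naming rule took, which leaves out gene models without a proper name, the largest change in bone marrow was in Vill, which encodes a villin-like protein: it fell from 32.4 ± 1.75 CPM in WT to 0.136 ± 0.181 CPM in K74R (log2 fold change -7.82, SE 0.36, n = 3 and 3). Per1, a gene of the circadian clock, rose from 21.8 ± 4.43 to 71.4 ± 4.65 CPM (1.72, SE 0.14). Dsp, which encodes the desmosomal protein desmoplakin, rose from 2.26 ± 0.263 to 13.9 ± 0.897 CPM (2.61, SE 0.17), and Lypd6b from 0.272 ± 0.0909 to 4.56 ± 1.47 CPM (4.05, SE 0.41). Erfe, which encodes the erythroblast hormone erythroferrone, fell from 9.77 ± 4.33 to 1.78 ± 0.909 CPM (-2.44, SE 0.44). The adjusted p of these genes in that order was 1.3e-05, 0.00106, 0.000261, 0.00447 and 0.0475 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The other large rises among these genes were in Eif3j2 (4.02), Ighv13-2 (2.47), Ighv7-1 (2.19), Mst1r (2.16), Ttc30b (2.15), Cdkl2 (2.07) and Amd2 (1.84). Mst1r, the receptor of macrophage-stimulating protein, rose from 1.45 ± 0.472 to 6.50 ± 1.41 CPM. The other large falls were in Gbp2b (-3.67), Vmn2r97 (-2.54), Muc20 (-2.08), Rab6b (-2.01), Igkv4-57-1 (-1.95), Igkv4-57 (-1.82), Kcnh7 (-1.47) and Ighg1 (-1.38). Ighg1, a heavy chain constant gene of class-switched antibodies, fell from 67.0 ± 8.76 to 25.7 ± 4.63 CPM. Eif3j2, Amd2, Ttc30b, Gbp2b, Vmn2r97 and the immunoglobulin segments have close copies in the genome, and their values are uncertain because the handling of shared reads is not given in the sources used here.

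In all, 115 of 14872 genes tested in bone marrow passed (76 higher and 39 lower in K74R), 59 of them by at least 2-fold, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 there were 2646 genes, where chance gives 744. The libraries of the genotypes did not overlap in 22.9% of the genes tested, where chance gives 10%. DESeq2 called 487 genes and limma-voom 80. The count was 46 without WT library 1, 684 without WT library 2, 11 without WT library 3, 16 without K74R library 2 and 21 without K74R library 3, and 60 with all 16 libraries in a single model. Of the 30 named genes that changed, the calls of 15 were kept without WT library 1, 6 without WT library 3, 25 without K74R library 1, 6 without K74R library 2 and 10 without K74R library 3. Limma-voom kept 23 of the 30 and all 16 libraries in a single model 13. Among the 17 lost in that model were Ighg1 (adjusted p = 0.299), Pdk1 (0.283), Gbp2 (0.278), Zfp36 (0.235), Gbp2b (0.130) and Dusp1 (0.127). Vill, Per1, Dsp and Lypd6b passed in all 20 alternatives run in bone marrow, with a highest adjusted p of 9.5e-04, 0.0150, 0.00656 and 0.0358. The log2 fold change of Vill was -9.61 without K74R library 3. Of the 20 alternatives Ighg1 passed in 19, Kcnh7, Mst1r and Vmn2r97 in 18, Amd2, Dusp1, Gbp7, Igkv4-57-1 and Zfp36 in 17, and Muc20, Rab6b and Ttc30b in 16. Cd200, Ear6, Gbp2, Gbp2b, Ighv7-1 and Pdk1 passed in 15, Eif3j2, Epx and Ighv13-2 in 14, Igkv4-57 in 13 and Cdkl2 in 12. Cdkl2 lost its call with limma-voom (0.0587), the replicate block (0.0614) and the block with length and GC offsets (0.0598). It also lost it without WT library 1 (0.106) or 3 (0.182) or K74R library 1 (0.0583), 2 (0.176) or 3 (0.203). Beside the single model, Gbp2b lost its call without WT library 1 (0.0708) or 3 (0.160) or K74R library 2 (0.212) or 3 (0.115). Its log2 fold change was -4.97 without K74R library 1 and -3.12 without K74R library 3. Erfe passed in 10 of the 20. It lost its call with limma-voom (0.110), robust dispersion (0.0731), library size alone (0.0538), a stricter filter (0.0512), all 16 libraries in a single model (0.0721) and length and GC offsets (0.0509). It also lost it without WT library 1 (0.114) or 3 (0.197) or K74R library 2 (0.224) or 3 (0.203).

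**Figure D1:**
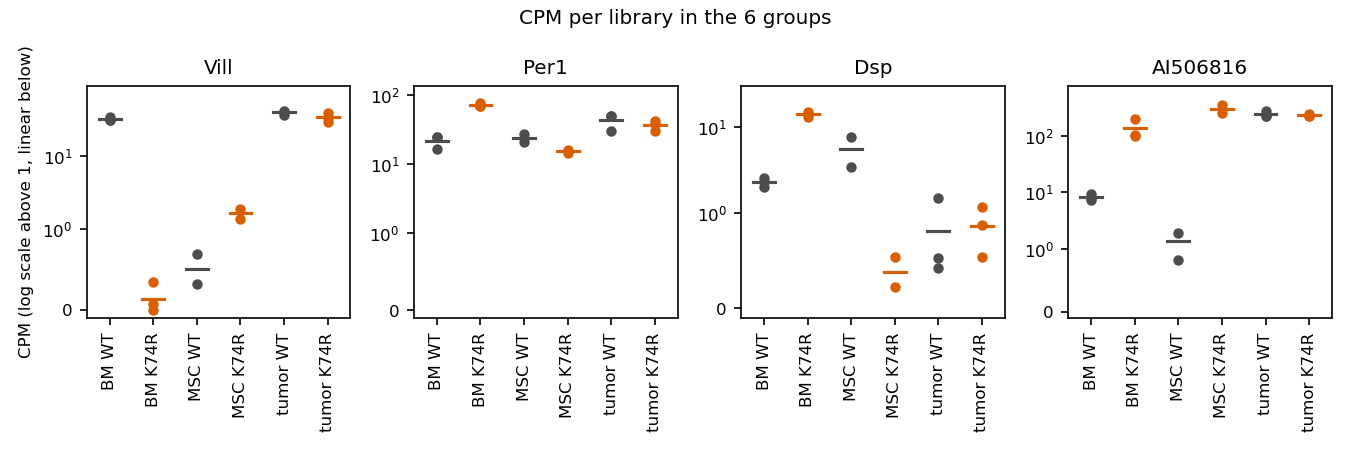
CPM on a symmetric log axis of Vill, Per1, Dsp and AI506816 in each library of the 6 groups, a point per library and a dash for the group mean. Vill stood at 32.4 CPM in WT and 0.136 CPM in K74R bone marrow, and AI506816 rose from 8.20 to 135.7 CPM in bone marrow.

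B cell genes stood higher as a group in K74R bone marrow. All 27 members tested had a positive log2 fold change, with a median of 0.73, and their summed level was 2046, 2915 and 1722 CPM in WT and 3078, 4017 and 4134 CPM in K74R. Over all genes 0 of the 27 passed with edgeR, 22 rose adjusted over the list alone, and 23 had an unadjusted p under 0.05 (all higher). DESeq2 called 6, and limma-voom 0. Rag1, which cuts antigen receptor genes in developing lymphocytes, had 70.3 ± 35.2 CPM in WT and 188.7 ± 36.6 CPM in K74R (adjusted p = 0.0798), and Cd22, a B cell surface receptor, 30.9 ± 5.87 and 50.2 ± 6.10 CPM (adjusted p = 0.0727), both by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The camera test of the list gave an adjusted p of 1.4e-19 with its preset correlation, and adjusted p = 0.590 with an estimated correlation.

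Mast cell, basophil and eosinophil genes were also displaced upward, with 3 of 16 members risen over all genes, 8 risen and 1 fallen adjusted over the list alone, and a median of 0.33 (camera adjusted p = 3.0e-07, and adjusted p = 0.590 with an estimated correlation). Epx, the eosinophil peroxidase, rose from 195.3 ± 18.4 to 309.7 ± 40.7 CPM (0.66) and Ear6, an eosinophil ribonuclease with close copies, from 107.0 ± 8.14 to 167.6 ± 22.0 CPM (0.65), with adjusted p = 0.0349 and 0.0341 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Il5ra, the interleukin-5 receptor chain, was the other riser. The T cell list (24 members, median 0.44, camera adjusted p = 0.00372), the dendritic cell list (16 members, 0.32, 6.6e-04) and the osteoblast list (14 members, 0.49, 0.00146) were displaced the same way, each with adjusted p = 0.590 with an estimated correlation. None of these 3 lists had a member past the threshold over all genes with edgeR, while 5 members of each were higher at an unadjusted p under 0.05. DESeq2 called 1, 1 and 2 of them, limma-voom 0, and adjusted over the list alone 0, 2 and 1 rose. The osteoblast call was lost without WT library 1 (adjusted p = 0.0512; 0.590 was the highest over its alternatives).

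Neutrophil genes were displaced downward in K74R bone marrow: 20 of 24 members had a negative log2 fold change, with a median of -0.17 and a camera adjusted p of 3.8e-06, and adjusted p = 0.590 with an estimated correlation. Their summed level was 46740, 43060 and 46060 CPM in WT and 39380, 38030 and 36070 CPM in K74R. With edgeR 0 members passed over all genes, 11 fell and 1 rose adjusted over the list alone, and 11 were lower and 1 higher at an unadjusted p under 0.05. DESeq2 called 9 lower and 1 higher, and limma-voom 0. Ms4a3, a marker of granulocyte and monocyte progenitors, had 157.4 ± 24.4 CPM in WT and 105.0 ± 5.80 CPM in K74R, and Csf3r, the receptor of granulocyte colony-stimulating factor, 292.6 ± 31.9 and 395.6 ± 21 CPM. Their adjusted p was 0.0571 and 0.0803 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

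**Figure D2:**
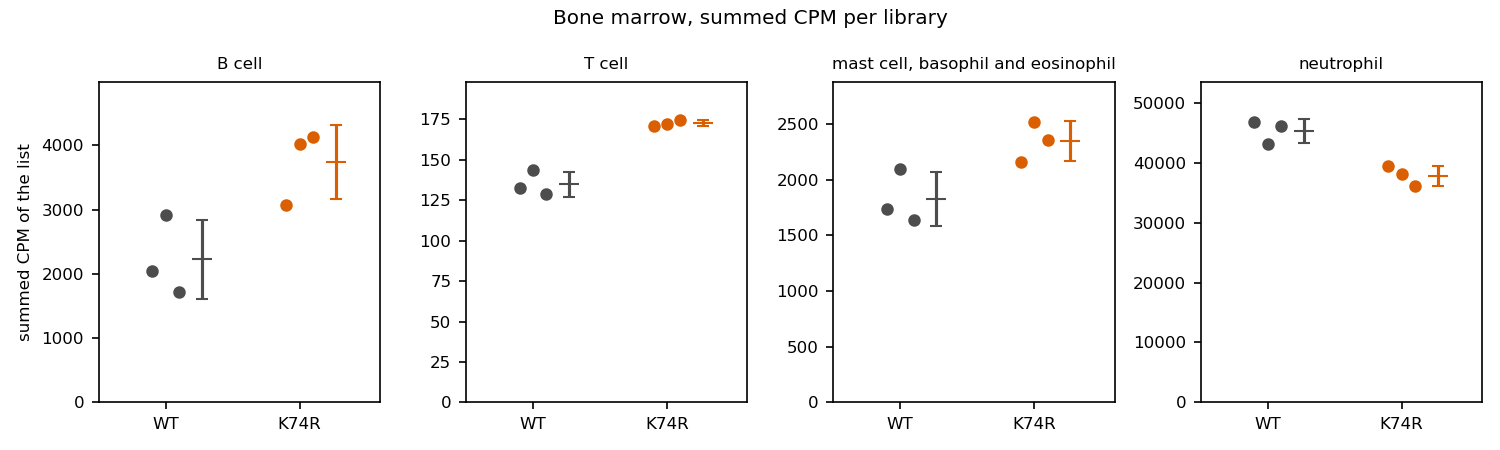
Summed CPM of the B cell, T cell, mast cell, basophil and eosinophil, and neutrophil lists in each bone marrow library, a point per library with the mean and SD of each genotype. The K74R libraries held 3078 to 4134 CPM of B cell transcripts against 1722 to 2915 CPM in WT, and 36070 to 39380 CPM of neutrophil transcripts against 43060 to 46740 CPM.

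Nuclear genes of the respiratory chain and ATP synthase were lower together, with a negative log2 fold change in all 39 members tested and a median of -0.21 (camera adjusted p = 2.4e-08, and adjusted p = 0.590 with an estimated correlation). None of them passed over all genes with edgeR, DESeq2 or limma-voom, none fell adjusted over the list alone, and 16 were lower at an unadjusted p under 0.05. With length and GC offsets the median of this list was -0.11 (camera adjusted p = 4.1e-04 with the preset correlation). Hypoxia and glycolysis genes had a median of -0.21 over 20 members (camera adjusted p = 6.6e-04, and adjusted p = 0.590 with an estimated correlation), with 1 fallen over all genes and 8 fallen and 1 risen adjusted over the list alone. The member that fell was Pdk1, which restrains pyruvate entry into mitochondria, from 61.6 ± 0.606 to 36.6 ± 6.37 CPM (-0.75, adjusted p = 0.0301 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of 42 interferon-stimulated genes 2 fell over all genes and 4 adjusted over the list alone, with a median of -0.12 (camera adjusted p = 0.00146, and adjusted p = 0.737 with an estimated correlation). Those 2 were the guanylate-binding protein genes Gbp7, from 166.9 ± 14.1 to 67.4 ± 16.3 CPM (-1.31), and Gbp2, from 21.7 ± 1.06 to 12.7 ± 0.639 CPM (-0.77), members of a family with close copies. The mitochondrially encoded transcripts had a median of -0.15 over 13 members (camera adjusted p = 0.0218, and adjusted p = 0.795 with an estimated correlation, 0 members past the threshold with edgeR, 2 lower at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma-voom). The interferon call was lost without WT library 2 (adjusted p = 0.0738), and the mitochondrial call without WT library 1 (0.0519), WT library 3 (0.312), K74R library 1 (0.113) or K74R library 3 (0.0817) and with length and GC offsets (0.44), with 0.795 the highest over its alternatives and 0.737 over those of the interferon list.

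Erythroid and Klf1 target genes were not displaced in bone marrow (37 members, median -0.10, camera adjusted p = 0.181). Bcl11a, a repressor of fetal and embryonic globin genes, rose from 76.8 ± 3.39 to 102.5 ± 5.11 CPM (0.42, adjusted p = 0.0454 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and was the sole member past the threshold. Bcl11a passed in 9 of 20 alternatives. Its adjusted p was 0.0511 with library size alone, 0.0521 with limma-voom, 0.474 with all 16 libraries in a single model, 0.0593 with the replicate block, 0.0555 with length and GC offsets and 0.0533 with both of these. It was 0.0858 and 0.214 without WT library 1 or 3, and 0.0749, 0.175 and 0.212 without K74R library 1, 2 or 3. Among checkpoint genes Cd200, whose product inhibits myeloid cells, rose from 4.49 ± 0.393 to 10.5 ± 1.55 CPM (1.23, adjusted p = 0.0215) in a list that was not displaced (22 members, camera adjusted p = 0.181). Among immediate early and heat shock genes, which respond to handling, Dusp1 rose from 24.1 ± 4.94 to 53.1 ± 10.6 CPM (1.14, adjusted p = 0.0301) and Zfp36 from 46.2 ± 3.96 to 81.6 ± 9.01 CPM (0.82, adjusted p = 0.0116), again without a call for the list (13 members, camera adjusted p = 0.181). In all, camera called 10 of 29 lists in bone marrow with the preset correlation (5 up and 5 down), 0 with an estimated correlation, and the 1-directional rotation test fry called 1, the T cell list (adjusted p = 0.0366). Of the 19 lists without a call, median, mean and camera direction differed in sign for 4: the KLF family, monocyte and macrophage, hematopoietic stem and progenitor, and skeletal muscle lists.

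**Figure D3:**
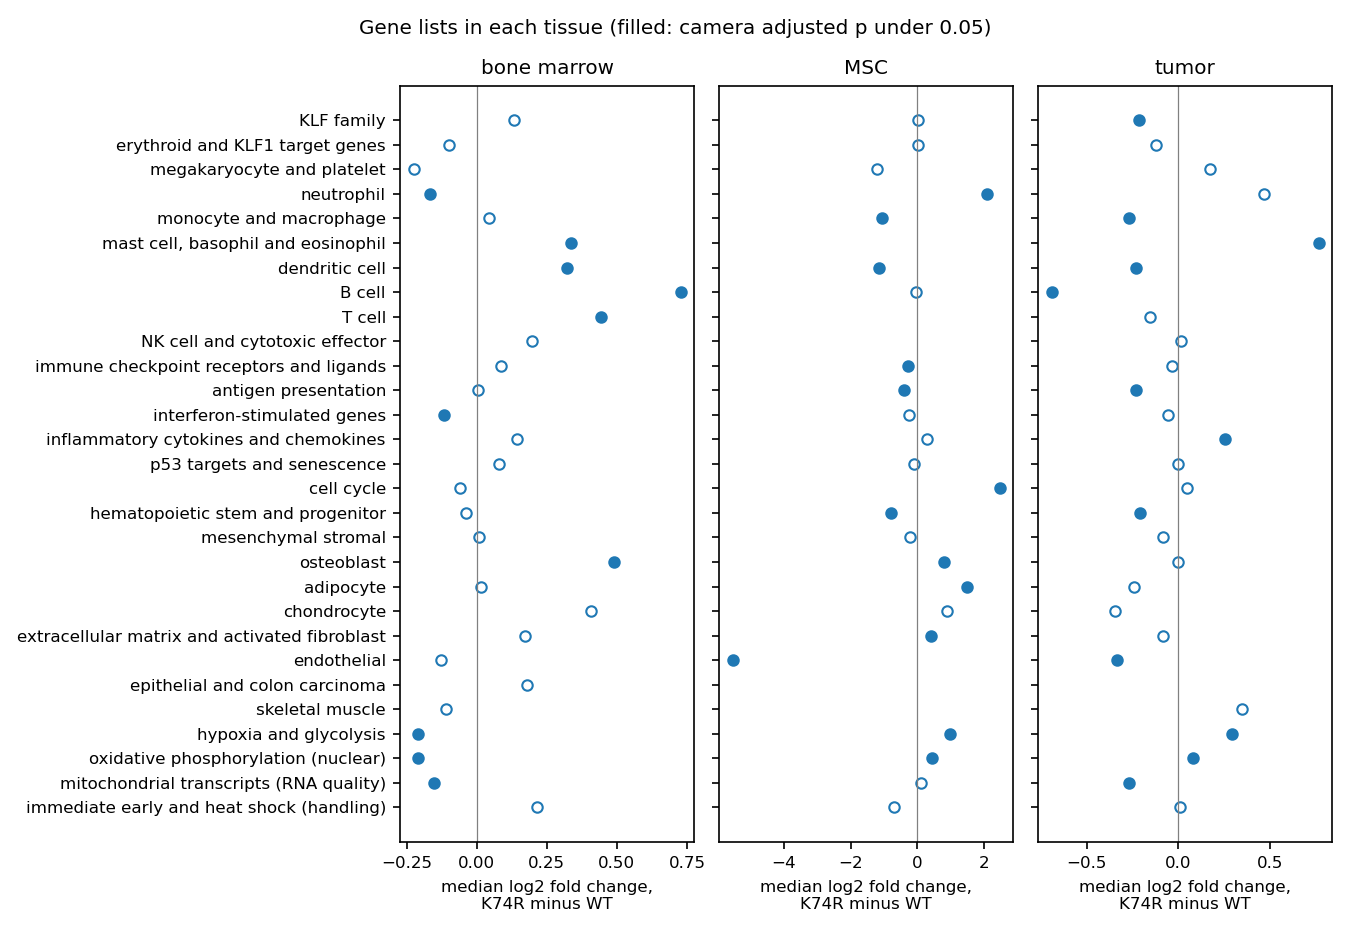
Median log2 fold change (K74R over WT, horizontal axis) of the members of each gene list in bone marrow, MSC and tumor, a point per list and tissue, filled where the camera adjusted p is under 0.05 with the preset correlation. The cell cycle list stood at 2.47 and the endothelial list at -5.54 in MSC.

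In MSC, cell cycle transcripts were higher in K74R. Birc5, which encodes the mitotic protein survivin, rose from 4.33 ± 0.898 to 36.8 ± 2.80 CPM (log2 fold change 3.08, SE 0.24, n = 2 and 2), and Mcm6, a subunit of the replicative helicase, from 30.5 ± 1.77 to 146.4 ± 2.42 CPM (2.26, SE 0.17). Of 35 cell cycle genes 28 rose over all genes and 34 adjusted over the list alone, none fell, and the median was 2.47 (camera adjusted p = 5.8e-55, and adjusted p = 0.414 with an estimated correlation and 0.0476 with fry). Their summed level was 767 and 548 CPM in WT and 2485 and 2873 CPM in K74R. Lmnb1, the lamin whose loss marks senescence, rose from 12.3 ± 1.42 to 60.2 ± 2.45 CPM (2.29). For each of the 3 genes the adjusted p was 0.0196 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The p53 and senescence list, which holds Lmnb1, was not displaced (23 members, camera adjusted p = 0.996).

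Genes of fat cells were also higher in K74R MSC. Plin1, which encodes the lipid droplet protein perilipin, rose from 2.31 ± 2.12 to 86.2 ± 4.31 CPM (5.20, SE 0.64), and Fabp4, a fatty acid carrier, from 38.8 ± 14 to 443.0 ± 26.3 CPM (3.51, SE 0.31), with adjusted p = 0.0271 and 0.0196 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The log2 fold change of Plin1 was 6.71 without WT library 1 and 4.50 without WT library 2. Of 18 adipocyte genes 4 rose over all genes and 11 adjusted over the list alone, with a median of 1.47 (camera adjusted p = 4.3e-09; adjusted p = 0.414 with an estimated correlation and 0.0454 with fry). Among 28 extracellular matrix genes 3 rose, the collagen VI chains, and 8 adjusted over the list alone (median 0.40, camera adjusted p = 7.9e-04, and adjusted p = 0.414 with an estimated correlation). Col6a3 rose from 294.9 ± 28.9 to 1832 ± 555 CPM (2.64) and Col6a2 from 364.3 ± 104.2 to 1266 ± 4.13 CPM (1.80). The osteoblast list had a median of 0.81 over 18 members (camera adjusted p = 0.00516, and adjusted p = 0.414 with an estimated correlation), although its sole member past the threshold over all genes was Tnfrsf11b, the decoy receptor osteoprotegerin, which fell from 327.6 ± 26.7 to 95.5 ± 21.5 CPM (-1.78). Adjusted over the list alone 4 osteoblast genes rose and 1 fell.

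Endothelial transcripts were much lower in K74R MSC. Pecam1, which encodes the junction protein CD31, fell from 310.4 ± 301 to 3.08 ± 0.442 CPM (-6.65, SE 0.92), and Erg, an endothelial transcription factor, from 30.3 ± 24.7 to 0.293 ± 0.182 CPM (-6.68, SE 0.89), with adjusted p = 0.0323 and 0.0315 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of 20 endothelial genes 9 fell over all genes and 19 adjusted over the list alone, with a median of -5.54 (camera adjusted p = 1.3e-18; adjusted p = 0.44 with an estimated correlation). Their summed level was uneven within WT, 1043 CPM in library 1 and 3788 CPM in library 2, against 213 and 459 CPM in K74R. Among the genes that the naming rule took, endothelial genes made up much of the largest falls, which were in Fgd5, Kmo, Myct1 (-6.85), Tek (-6.68), Erg, Pecam1, Emcn (-6.63), Cdh5 (-6.55), She (-6.42) and Tie1 (-6.35). Fgd5 had 3 counts in K74R and was 214-fold lower (95% counting interval 72.9 to 1041), and Kmo, with 2 counts, was 137.4-fold lower (37.7 to 1141). Without WT library 2 the log2 fold changes of the endothelial ones were smaller in size, with She at -4.61 and Pecam1 at -4.98, and without WT library 1 they were larger, with She at -7.20 and Pecam1 at -7.41. Fgd5 passed in 11 of 18 alternatives and She in 10. Both lost their calls with relative log expression factors (adjusted p = 0.0501 and 0.0520), library size alone (0.0592 and 0.0621), limma-voom (0.142 each), robust dispersion (0.0512 and 0.0525) and length and GC offsets (0.0523 and 0.0559). Both also lost them without K74R library 1 (0.222 and 0.218) or 2 (0.0933 and 0.103), and She with a stricter filter (0.0518). With limma-voom 0 of the 20 endothelial genes passed, DESeq2 called 18, and 19 had an unadjusted p under 0.05 with edgeR. Fgd5, Myct1 and Cd34, markers of stem cells that endothelial cells share, were the fallen members of the hematopoietic stem and progenitor list (14 members, 6 fallen and 3 risen adjusted over the list alone, median -0.81, camera adjusted p = 0.00905, 0.521 with an estimated correlation). The call of that list was lost without K74R library 2 (adjusted p = 0.0996, where 0.521 was the highest over its alternatives).

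Most members of the macrophage and antigen presentation lists were lower in K74R MSC. A positive log2 fold change was found in 8 of 23 and 2 of 20 of them. Cd5l and Marco, macrophage genes outside the list, rose. Ms4a7, a macrophage surface gene, fell from 325.5 ± 52.6 to 57.7 ± 2.52 CPM (-2.50, SE 0.21). Arg1, the arginase of alternatively activated macrophages, went the other way, from 17.7 ± 5.61 to 227.5 ± 160.1 CPM (3.68, SE 0.58). Its log2 fold change was 4.27 without K74R library 1 and 2.69 without K74R library 2. Arg1 passed in 14 of 18 alternatives and lost its call with library size alone (adjusted p = 0.0534), with length and GC offsets (0.0542) and without WT library 2 (0.0504) or K74R library 1 (0.0933). Of 23 monocyte and macrophage genes 4 fell and 1 rose over all genes, 12 fell and 1 rose adjusted over the list alone, and the median was -1.07 (camera adjusted p = 1.2e-05, and adjusted p = 0.555 with an estimated correlation). Cd74, the invariant chain of class II molecules, fell from 76.2 ± 20.6 to 6.17 ± 0.373 CPM (-3.62, SE 0.27) and the class II gene H2-Aa from 12.6 ± 4.55 to 0.626 ± 0.120 CPM (-4.31, SE 0.43). With H2-Eb1 they were the 3 of 20 antigen presentation genes that fell, and 6 fell adjusted over the list alone (median -0.40, camera adjusted p = 7.5e-07, and adjusted p = 0.521 with an estimated correlation). The dendritic cell list fell in 1 of 7 members, Itgax (-2.21), and 6 fell and 1 rose adjusted over the list alone (median -1.14, camera adjusted p = 1.3e-04, and adjusted p = 0.414 with an estimated correlation). The checkpoint list fell in 2 of 16, Entpd1 (-2.28), an ectoenzyme that degrades ATP, and Vsir (-1.50), with 6 fallen and 1 risen adjusted over the list alone (median -0.28, camera adjusted p = 0.00725, and adjusted p = 0.414 with an estimated correlation). The adjusted p of the named genes lay between 0.0196 and 0.0392 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

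**Figure D4:**
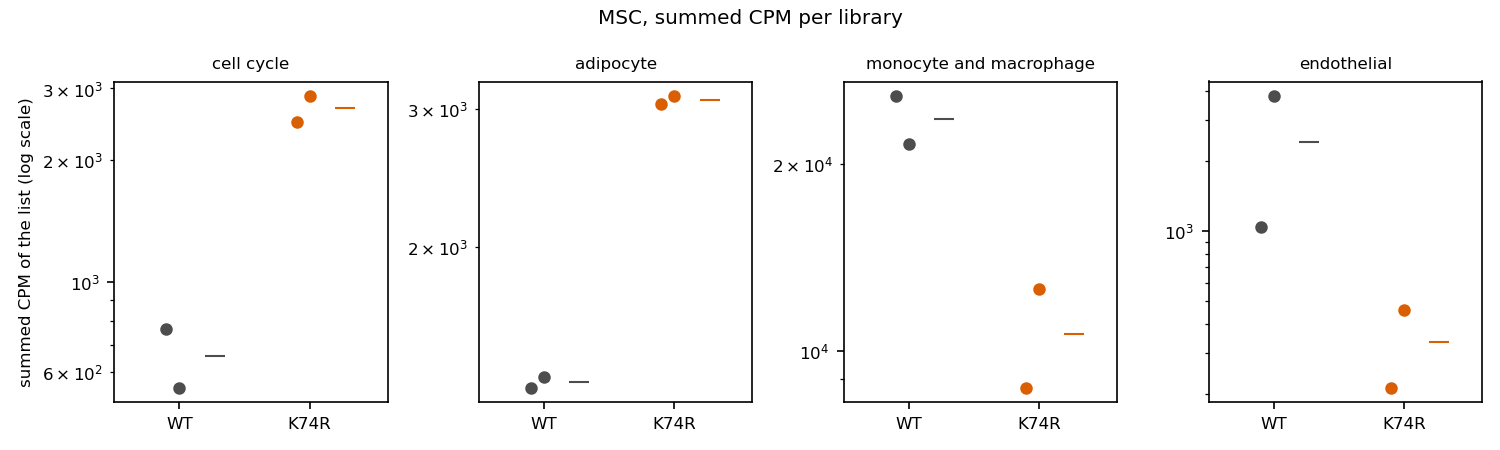
Summed CPM (log axis) of the cell cycle, adipocyte, monocyte and macrophage, and endothelial lists in each MSC library, a point per library and a dash for the mean of each genotype. Cell cycle transcripts summed to 548 and 767 CPM in WT and 2485 and 2873 CPM in K74R, and endothelial transcripts to 1043 and 3788 CPM against 213 and 459 CPM.

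Other large rises in K74R MSC were in Ear2, an eosinophil ribonuclease with close copies, which had 0 counts in WT and 6.51 ± 1.39 CPM in K74R, at least 72.2-fold higher against a floor of 3 counts over the group. Cd5l (6.85), which encodes a secreted macrophage protein, Rab3b, Cd200r4, Tmem266, Lipo2, Itih2 (5.47), Gpd1 (5.16) and the scavenger receptor gene Marco (5.14, from 2.04 to 72.6 CPM) also rose, with adjusted p between 0.0155 and 0.0403 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Rab3b, Cd200r4, Tmem266 and Lipo2 had 3, 2, 1 and 2 counts in WT, and their K74R levels were 64.2-fold (95% counting interval 21.7 to 313.8), 62.0-fold (16.8 to 517), 64.8-fold (11.3 to 2597) and 51.0-fold (13.8 to 426.5) those of WT. Over the alternatives their log2 fold changes ran from 4.99 to 9.60, 4.82 to 9.03, 4.79 to 8.07 and 5.08 to 5.75. Without WT library 1 the log2 fold change was 8.17 for Itih2, 7.995 for Gpd1 and 5.84 for Marco. Without WT library 2 it was 4.61 for Itih2 and 4.29 for Gpd1. Tmem266 lost its call without either (adjusted p = 0.0764 and 0.0664). Of 4 mast cell, basophil and eosinophil genes 3 rose, Ear2, Ccr3 (3.07) and Mcpt8, in a list too small for camera. The neutrophil list had a median of 2.09 over 8 members, with Mmp8, a neutrophil collagenase, risen (4.27) and Csf3r fallen (-1.72), and 5 risen and 1 fallen adjusted over the list alone (camera adjusted p = 6.4e-04, and adjusted p = 0.414 with an estimated correlation). Csf3r passed in 11 of 18 alternatives. It lost its call with library size alone (adjusted p = 0.0558), length and GC offsets (0.0546) and these with the replicate block (0.0710), and without WT library 1 (0.0759) or 2 (0.0503) or K74R library 1 (0.180) or 2 (0.0546). Hypoxia and glycolysis genes had a median of 0.97 over 23 members (camera adjusted p = 2.8e-06) and respiratory chain genes 0.44 over 39 (5.0e-05), with adjusted p = 0.555 and 0.575 with an estimated correlation. With length and GC offsets these medians were 0.97 and 0.23. In these last lists 0 members passed over all genes with edgeR and 0 with limma-voom, 15 of each were higher at an unadjusted p under 0.05, and DESeq2 called 12 and 3. Adjusted over the list alone 4 hypoxia genes and 0 respiratory chain genes rose. Single genes past the threshold in lists without a call were Rab27b (2.00), Krt7 (3.62), Tal1 (-1.74), Cxcl16 (-1.40) and Nr4a1 (-2.03), with adjusted p = 0.0394, 0.0270, 0.0497, 0.0319 and 0.0361 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. They passed in 13, 17, 6, 15 and 14 of 18 alternatives. Tal1 lost its call with each other scaling, a stricter filter, limma-voom, robust dispersion and length and GC offsets and without any 1 of the libraries (highest adjusted p = 0.203).

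In all, 484 of 14475 genes passed in MSC (297 higher and 187 lower in K74R), 483 of them by at least 2-fold, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. There were 3765 genes with an unadjusted p under 0.05, and the libraries of the genotypes did not overlap in 59.5% of genes, where chance gives 33.3%. DESeq2 called 1831 genes (941 higher and 890 lower) and limma-voom 406, and with all 16 libraries in a single model the count was 4431. Without K74R library 1 the count was 0 with edgeR (2109 at an unadjusted p under 0.05), 0 with limma-voom and 571 with DESeq2, and without WT library 2 it was 253 with edgeR. In these fits the single sample left in a genotype is assumed to vary like the others. Of the 43 named calls 38 were kept without WT library 1, 31 without WT library 2, 0 without K74R library 1 and 26 without K74R library 2. Limma-voom kept 31 of the 43, library size alone 34 and length and GC offsets 37. Camera called 13 of 24 lists in MSC (7 up and 6 down), 0 with an estimated correlation, and fry called 3, the cell cycle, adipocyte and megakaryocyte lists. Of the 11 lists without a camera call, median, mean and camera direction differed in sign for 3: the KLF family, erythroid, and p53 and senescence lists. Since macrophage and endothelial transcripts differed between the genotypes, changes of expression and of cell content cannot be told apart among the MSC calls. Should the letters KCF and KLF in the MSC column names mark a batch, it could not be told apart from genotype.

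In tumors 6 of 14779 genes passed and all 6 were lower in K74R. Lars2, which encodes the mitochondrial leucyl-tRNA synthetase, fell from 1633 ± 215 to 569.3 ± 101.8 CPM (-1.52, SE 0.14, n = 3 and 3), and mt-Nd6, the complex I subunit gene on the light strand of the mitochondrial genome, from 1131 ± 57.7 to 615.1 ± 72.4 CPM (-0.88, SE 0.09), with adjusted p = 0.0174 and 0.0260 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The other 4, gene models without a proper name and named here after their values were seen, were CT010467.1 (-1.69), which is annotated as ribosomal RNA, Gm23935 (-1.59), Gm15564 (-1.53) and Gm24270 (-1.51). Gene models that kept a constant ratio to CT010467.1 over the bone marrow libraries, Lars2 among them, took 1.03, 1.08 and 1.34% of the counts in the WT tumor libraries and 0.292, 0.377 and 0.434% in the K74R ones. In bone marrow the same models took 0.267, 0.234 and 1.04% in WT and 1.20, 0.937 and 0.646% in K74R, and in MSC 0.319 to 0.369%. The gene mt-Nd6 lies on the strand opposite to the other mitochondrial protein-coding genes and overlaps the end of mt-Nd5, and its value is uncertain because the strand setting is not given in the sources used here.

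**Figure D5:**
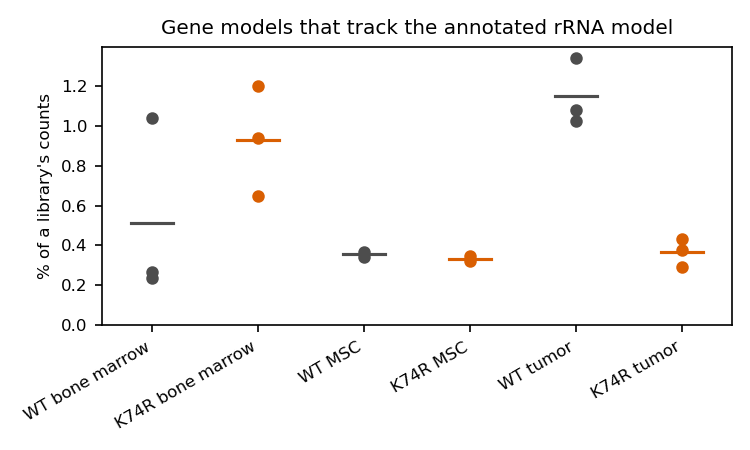
Share of counts, in percent, in the gene models that kept a constant ratio to the annotated ribosomal RNA model over the bone marrow libraries, a point per library in the 6 groups and a dash for the group mean. WT tumor libraries stood at 1.03 to 1.34% and K74R tumor libraries at 0.292 to 0.434%.

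At an unadjusted p under 0.05 there were 1661 genes in tumors, the libraries of the genotypes did not overlap in 17.1% of genes, where chance gives 10%, and DESeq2 called 209 genes (52 higher and 157 lower) and limma-voom 6. With edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the count was 124 without K74R library 1 (18 higher and 106 lower). It was 0 without any 1 of the WT libraries, without K74R library 2 and with all 16 libraries in a single model, where 1044, 936, 2147, 1593 and 1386 genes had an unadjusted p under 0.05. There DESeq2 called 53, 74, 259, 183 and 63 genes and limma-voom 0 in each. Lars2 passed in 14 of 19 alternatives (highest adjusted p = 0.398) and mt-Nd6 in 13 of 19 (0.166), and both lost their calls in those 5 settings. The sixth loss of mt-Nd6 came when the models that track ribosomal RNA, which do not include it, were removed. Its log2 fold change was -0.88 (SE 0.09) before and after, and its adjusted p went from 0.0260 to 0.09995. The call ended because the genes with smaller p were among those removed, which changed the rank of its p from 4 to 1 in the Benjamini-Hochberg adjustment.

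Several cell type lists were displaced downward in K74R tumors, without a member past the threshold over all genes by edgeR or limma-voom. A library batch that the letter R in the WT tumor columns may mark cannot be told apart from genotype. This limit holds for every tumor count, list and contrast given here. In the monocyte and macrophage list 10 of 24 members fell adjusted over the list alone, with a median of -0.27 (camera adjusted p = 2.1e-07, and adjusted p = 0.256 with an estimated correlation). Its member Adgre1, which encodes the macrophage marker F4/80, had 97.0 ± 4.18 CPM in WT and 55.6 ± 12 CPM in K74R, and Ms4a7 46.0 ± 1.17 and 27.9 ± 5.23 CPM, both with adjusted p = 0.194 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In the B cell list 7 of 13 fell adjusted over the list alone, with a median of -0.69 (camera adjusted p = 1.0e-07, and adjusted p = 0.256 with an estimated correlation), and Ighm had 18.1 ± 1.23 and 6.77 ± 2.35 CPM (adjusted p = 0.194). Endothelial genes had a median of -0.33 over 21 members, with 1 fallen adjusted over the list alone (camera adjusted p = 1.4e-05, and adjusted p = 0.256 with an estimated correlation), and Pecam1 had 52.7 ± 4.43 and 38.0 ± 2.97 CPM (adjusted p = 0.222). KLF genes had a median of -0.22 over 14, with 5 fallen adjusted over the list alone (camera adjusted p = 0.00156, and adjusted p = 0.256 with an estimated correlation), and Klf11 and Klf4 had log2 fold changes of -0.67 and -0.51 (adjusted p = 0.222 and 0.267). At an unadjusted p under 0.05 the lower members of these 4 lists numbered 10, 7, 8 and 5, and DESeq2 called 6, 2, 2 and 3.

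The antigen presentation list (20 members, median -0.23, camera adjusted p = 5.1e-04), the dendritic cell list (14, -0.23, 0.0212), the hematopoietic stem and progenitor list (15, -0.21, 0.0277) and the mitochondrial transcripts (13, -0.27, 3.8e-07) were also displaced downward in K74R tumors. Their adjusted p in that order was 0.57, 0.425, 0.256 and 0.256 with an estimated correlation. Adjusted over the list alone 1 antigen presentation gene and 6 mitochondrial transcripts fell, and over all genes mt-Nd6 alone with edgeR and with limma-voom. Upward stood hypoxia and glycolysis genes (23 members, median 0.29, camera adjusted p = 9.1e-06), respiratory chain genes (39, 0.08, 9.2e-04), inflammatory cytokines and chemokines (23, 0.26, 0.0212) and mast cell, basophil and eosinophil genes (7, 0.76, 0.0212, with 1 risen adjusted over the list alone), with adjusted p = 0.57, 0.57, 0.504 and 0.504 with an estimated correlation in that order. At an unadjusted p under 0.05 the first 4 of these lists had 2, 3, 4 and 7 lower and 0 higher members. The other 4 had 4, 7, 4 and 2 higher ones, with 2 lower in the cytokine list and 0 in the rest, and DESeq2 called 1, 1, 0 and 5 lower and 0, 0, 1 and 0 higher. Among their members Ldha, which encodes a lactate dehydrogenase chain, had 1111 ± 75.8 CPM in WT and 1434 ± 232 CPM in K74R (adjusted p = 0.347 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and Cxcl1, a chemokine that attracts neutrophils, 12.7 ± 3.26 and 20.5 ± 4.49 CPM (adjusted p = 0.347). Camera called 12 of 28 lists in tumors (4 up and 8 down) with the preset correlation, 0 with an estimated correlation, and fry 0. Of the 16 lists without a call, median, mean and camera direction differed in sign for 4: the megakaryocyte, NK cell, p53 and senescence, and immediate early lists.

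Some of these tumor list calls rested on single libraries. Without WT library 2 the mast cell list had adjusted p = 0.0594, the cytokine list 0.264 and the stem and progenitor list 0.0647. Without WT library 3 the dendritic cell list had 0.417 and the hypoxia list 0.051. Without K74R library 1 the stem and progenitor list had 0.144, and without K74R library 2 the mast cell list had 0.272, the antigen presentation list 0.256 and the cytokine list 0.229. Without K74R library 3 the mast cell list had 0.102, the dendritic cell list 0.485 and the hypoxia list 0.0667. With offsets for transcript length and GC the cytokine list had 0.118 and the respiratory chain list 0.576.

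Across tissues the genotype effect itself was compared by an interaction contrast in a single model of all 16 libraries and 18191 genes. Vill fell by 7.82 on the log2 scale in bone marrow and had a log2 fold change of -0.23 in tumors, a difference of -7.61 (adjusted p = 6.1e-07 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and the difference between bone marrow and MSC was -9.52 (adjusted p = 4.2e-07). The cell cycle genes Nek2, Birc5 and Mcm6 differed between bone marrow and MSC by -2.56, -3.12 and -2.47 and between MSC and tumors by 2.56, 3.05 and 2.29. The effect differed in 7 genes between bone marrow and tumors (5 more positive and 2 more negative in bone marrow), in 3428 between bone marrow and MSC (1464 and 1964) and in 1930 between MSC and tumors (1178 more positive and 752 more negative in MSC). This model shares its estimate of the spread over the tissues, and in the separate fits the biological coefficient of variation was 24.4% in MSC against 13.1% in bone marrow and 13.9% in tumors. The contrasts with MSC rest on a spread pooled with tissues that varied less than MSC, and the same model called 4431 genes in MSC where the separate fit called 484. Differences in cell content between the MSC genotypes may also enter these contrasts. Tumor counts include those of MC38 cells, so a small effect there need not show a small effect in cells of the mouse. Without WT bone marrow library 1 or 2 the first count was 4 each, without WT bone marrow library 3 it was 12, without K74R bone marrow library 1 it was 20 and without K74R tumor library 1 it was 54. Without K74R MSC library 1 the second was 1938 and the third 1110, and without K74R MSC library 2 the third was 3030.

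Genes changed in both bone marrow and MSC numbered 11 of the 12840 tested in both. AI506816, Amd2, Ddit4 and Dhrs9 were higher in both (1.05 expected), Gm7324 and Rpl3-ps1 lower in both (0.390 expected), Bmf, Ctsk, Dsp and Gm49450 higher in bone marrow and lower in MSC (0.715 expected), and Spc24 the reverse. All of them are named because these counts are small, after their values were seen. The lowest adjusted p of the overlaps was 0.0675, for the genes higher in bone marrow and lower in MSC, by Fisher's exact test, one-sided, with Benjamini-Hochberg adjustment over 12 tests. In 4 of these tests a tumor list held 0 genes, which fixed their outcome, and over the other 8, a choice made after the result was seen, the same overlap had adjusted p = 0.0450 and the next, of genes higher in both, 0.0837. Genes changed the same way in bone marrow and tumors, or in MSC and tumors, numbered 0 with edgeR and 0 with limma-voom. At an unadjusted p under 0.05 those numbers were 109 and 459, and DESeq2 gave 7 and 66. No gene was called the same way in all 3 tissues by edgeR or limma-voom, 26 had an unadjusted p under 0.05 in each, and DESeq2 called 5. Numbers expected by chance at that unadjusted level are not given here, so 109, 459 and 26 do not by themselves show shared effects. Across the genes tested in both tissues, log2 fold changes had a Spearman correlation of -0.139 for bone marrow and tumors. It was 0.258 for MSC and tumors and -0.203 for bone marrow and MSC. The number of genes called the same way in bone marrow and MSC by edgeR, 6 with all libraries, was 17 without WT bone marrow library 2, 3 without WT bone marrow library 3 or K74R bone marrow library 2 or 3, 2 without either WT MSC library and 0 without K74R MSC library 1. Without K74R tumor library 1, 1 gene was called the same way in bone marrow and tumors and 14 in MSC and tumors.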

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

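The counts over other splits of the samples and the interaction contrasts were planned, but the number of splits drawn for the interaction was raised to 100 after the result of a smaller draw had been seen, and the tests of transcript length and GC, neutrophil share, ribosomal RNA, column letters, strain background, linkage, carried regions and gene copies were chosen after the results were seen.

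The genotype effect differed between tissues, by edgeR's quasi-likelihood test of the interaction with Benjamini-Hochberg adjustment, in 7 genes between bone marrow and tumors, 3428 between bone marrow and MSC and 1930 between MSC and tumors. The contrasts with MSC rest on a spread pooled with tissues that varied less than MSC. The monocyte and macrophage list summed to 25690 and 21500 CPM in WT and 8721 and 12570 CPM in K74R MSC. The endothelial list summed to 1043 and 3788 CPM against 213 and 459 CPM. Cell content and expression within cells thus cannot be told apart in the contrasts with MSC. Tumor counts also include those of MC38 cells. Between bone marrow and tumors the named genes were Vill (-7.61, adjusted p = 6.1e-07), Cdkl2 (2.15, 0.0194), Per1 (1.93, 0.0222) and Rhob (1.20, 0.0348). Vill passed in all 18 alternatives run for that contrast, Cdkl2 in 12, Per1 in 11 and Rhob in 8, with highest adjusted p of 0.184, 0.0915 and 0.159 for the last 3. Cdkl2 lost its call with the replicate block (0.121) and limma-voom (0.184) and without WT bone marrow library 1 (0.108), 2 (0.0557) or 3 (0.0515) or K74R bone marrow library 3 (0.0583). Per1 lost it with the block (0.0915) and without WT bone marrow library 1 (0.0530) or 2 (0.0557), K74R bone marrow library 2 (0.0756), WT tumor library 1 (0.0878) or 2 (0.0715) or K74R tumor library 3 (0.0672). Rhob, a small GTPase gene, lost it with the block (0.159) and limma-voom (0.0511) and without WT bone marrow library 1 (0.139), 2 (0.0571) or 3 (0.0696), K74R bone marrow library 2 (0.116) or 3 (0.0951), WT tumor library 1 (0.102) or 3 (0.0745) or K74R tumor library 3 (0.0672). Between bone marrow and MSC they were Nek2 (-2.56), Mcm6 (-2.47), Vill (-9.52), Birc5 (-3.12) and Cxcr4 (5.37). Between MSC and tumors they were Nek2 (2.56), Hjurp (2.98), Birc5 (3.05), Ercc6l (2.47) and Mcm6 (2.29), and the genes of these 2 contrasts passed in each of the 16 alternatives run for theirs. The count of 7 between bone marrow and tumors was reached by 10 of 100 drawn splits of the samples within tissues, the real one included, and another split gave 19, so chance is not excluded for that count.

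In K74R bone marrow B cell genes stood higher and neutrophil and respiratory chain genes lower by camera with its preset correlation, calls that were lost with an estimated correlation (adjusted p = 0.590 for each of the 3 lists). With offsets for transcript length and GC the B cell median was 0.80 (0.73 before) and the respiratory chain median -0.11 (-0.21 before), both lists still called with the preset correlation (adjusted p = 7.9e-22 and 4.1e-04), which argues against such a trend as the whole cause, although part of the respiratory chain shift went with it. A lower share of neutrophil RNA alone would raise other cell types alike, yet the B cell median lay 0.95 above the megakaryocyte median, more than the larger SD of the members (0.292). That SD is over genes and leaves out the spread between libraries. The megakaryocyte list summed to 1671, 3631 and 3280 CPM in WT and 2043, 2676 and 2847 CPM in K74R. Its median, -0.23, lay below those of the monocyte and macrophage list (0.04) and the erythroid list (-0.10). A higher share of B cells remains a candidate explanation, untested here because no cell counts are at hand, and a biological effect of the genotype is open. The 115 genes called in bone marrow compare with 2 for the highest of the other splits, and 1 of 10 splits reached the real count, too few splits for a share under 0.05.

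All 6 gene models called in tumors were lower in K74R. One of them is the annotated ribosomal RNA model, and for the 4 others apart from mt-Nd6 the SD of the log2 ratio to it over the bone marrow libraries was at most 0.193, against an SD of 1.02 for that model itself, so leftover ribosomal RNA is a candidate source of their reads, including those counted to Lars2. For mt-Nd6 the SD was 0.915, which argues against reads of ribosomal RNA as the source there. Whether its fall and theirs share a cause in library preparation is not tested by this ratio. The letter R was in 3 of 3 WT tumor columns and 0 of the K74R columns, so a library batch that it may mark and the genotype cannot be told apart, and a biological effect of the genotype is open. The highest of the other splits gave 0 genes against 6 for the real one, which 1 of 10 splits reached, too few splits for a share under 0.05.

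In bone marrow 27 genes were called with an absolute log2 fold change of at least 2, of which 18 were tested in MSC. A strain background carried with the allele that acts alike in both tissues would move a gene the same way in both. Of these genes 2, Dsp and Gm49450, were called in the opposite direction in MSC. Since cell content and expression cannot be told apart among the MSC calls, this does not decide whether such a background moved them. A background that acts differently by tissue or cell type, or that differs between mice of a genotype, is not excluded either. For the 3 called the same way, AI506816, Rpl3-ps1 and Gm7324, background and an effect of the genotype cannot be told apart, since both predict that direction. No KLF gene had more than 1 of the 27 within 20 Mb (1 for Klf1, where 0.550 is expected), which argues against a region linked to a KLF gene as the cause of the set, while 4 of them, Rab6b, Mst1r, Vill and Slc22a13b-ps, lay between 103111787 and 119231692 on chromosome 9, which holds no KLF gene, and whether a carried region there lies behind these 4 cannot be told apart from chance (permutation p = 0.0618, one-sided, over 10000 random sets of tested genes, whose densest window of 20 Mb held a median of 2). Pseudogenes were 6 of the 27 and 495 of the 14845 other genes tested (p = 0.00023 by Fisher's exact test, one-sided), so reads shared with gene copies may account for part of the set, while 21 were not pseudogenes and a biological effect of the genotype is open.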

How the results depend on the processing

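The offsets for transcript length and GC, the crossed block and the removal of ribosomal RNA models were chosen after the data were seen, and the other alternatives were planned. Where a value below differs from the reported one the cause was not tested. Outside leave-one-out, the values of named genes kept their side of the threshold in 1005 cases in bone marrow, 807 in MSC and 800 in tumors, lost it in 38, 41 and 3 and gained it in 46, 88 and 52. With all libraries 30 of 78, 43 of 67 and 2 of 62 of these genes were called. The cases kept thus include uncalled genes that stayed uncalled.

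Against 115, 484 and 6 genes in bone marrow, MSC and tumors, leaving out the filter on low counts gave 875, 3063 and 810, DESeq2 487, 1831 and 209, and all 16 libraries in a single model 60, 4431 and 0. The share of higher genes in MSC was 61.4% and became 49.6% without the filter, 51.4% with DESeq2, 45.3% without WT library 1 and 49.8% with the block. In tumors 0 of 6 genes were higher, against 36.2% without the filter and 24.9% with DESeq2. Removing ribosomal RNA models left 0 genes in tumors with edgeR and limma-voom, with 1656 at an unadjusted p under 0.05 and 202 by DESeq2, although mt-Nd6, not among the models removed, kept its log2 fold change of -0.88. For the effect difference between bone marrow and tumors (7) relative log expression factors gave 11 (9 more positive in bone marrow, against 5 of 7), no filter 603 and DESeq2 193 (160 more positive). Genes changed the same way in bone marrow and MSC (6) numbered 24 and 0 at thresholds of 0.1 and 0.01 and 39 with DESeq2, and with DESeq2 there were 7 in bone marrow and tumors, 66 in MSC and tumors and 5 in all 3 tissues.

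Leaving out each library in turn gave 11 to 684 genes in bone marrow, 0 to 581 in MSC and 0 to 124 in tumors. Effect differences ranged from 4 to 54 (bone marrow and tumors), 1938 to 4416 (bone marrow and MSC) and 1110 to 3030 (MSC and tumors). Shared genes ranged from 0 to 17 (bone marrow and MSC), 0 to 1 (bone marrow and tumors) and 0 to 14 (MSC and tumors). Changes of sign with a call were, by camera with its preset correlation, the mesenchymal stromal list in bone marrow without WT library 1 (adjusted p = 0.0342) and the adipocyte list in tumors without WT library 1 (0.00806). With all libraries these lists had adjusted p = 0.897 and 0.837 with an estimated correlation. Over all libraries left out these lists ranged from 0.0342 to 0.857 and from 3.1e-05 to 0.497.

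The replicate numbers gave no clear sign of pairing. Deviations of equally numbered libraries correlated across genes with r of 0.284, 0.138 and -0.103 in bone marrow, 0.028, -0.053 and 0.053 in tumors and -0.179 in MSC. Not every library correlated best with its own number. These values do not exclude that a number marks a shared batch. In MSC, with 2 libraries per genotype, every correlation has the same size by construction. With the replicate block the counts were 135, 1135 and 13, with the block and the offsets 14 in tumors, and genes shared by bone marrow and MSC numbered 16. The block ended the call of the stem and progenitor list in tumors (0.0573). With the numbers crossed in MSC 1943 genes were called. The median log2 fold change of all genes moved by less than 0.1 under every scaling.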

Other observations

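The tests of glucocorticoid and clock genes were chosen after the prompting genes were seen.

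Immunoglobulin genes in bone marrow moved both ways. Of 167 tested 8 changed, 5 up and 3 down in K74R, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Igha, the constant gene of IgA, rose from 118.3 ± 18.9 to 250.6 ± 58.8 CPM (log2 fold change 1.08), and the variable segments Igkv4-59 (1.5) and Ighv1-80 (1.48) rose beside Ighv13-2 and Ighv7-1, while Ighg1 and the variable segments Igkv4-57 and Igkv4-57-1 fell. Igha, Igkv4-59 and Ighv1-80 lie outside the naming rule and were chosen after their values were seen. All of these segments have close copies, so their values are uncertain.

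AI506816, a gene model without a proper name chosen after its values were seen, rose from 8.20 ± 1.09 to 135.7 ± 57.5 CPM in bone marrow and from 1.36 to 300.5 CPM in MSC, and stood at 241 and 235 CPM in WT and K74R tumors. The pseudogene Rpl3-ps1 fell from 55.0 to 6.14 CPM in bone marrow and from 68.5 to 7.61 CPM in MSC, with 16 and 12.2 CPM in WT and K74R tumors.

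Xist, transcribed from the inactive X chromosome, was low in every group, with 0.903 ± 0.240 and 0.491 ± 0.207 CPM in WT and K74R bone marrow, 0.120 ± 0.00695 and 0.145 ± 0.0502 CPM in MSC and 1.16 ± 0.318 and 2.09 ± 2.02 CPM in tumors. The K74R tumor mean rests on library 3, at 4.43 CPM, and was 0.928 CPM without it. The Y-linked Ddx3y had means of 120.5 and 112.7 CPM in WT and K74R bone marrow, 87.4 and 127.2 CPM in MSC and 16.7 and 13.9 CPM in tumors.

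Per1, Tsc22d3, Ddit4, Dusp1, Sik1 and Zfp36, which glucocorticoids induce, rose together in K74R bone marrow. Tsc22d3 rose from 49.3 to 119.8 CPM (1.28), Ddit4 from 4.88 to 14.9 CPM (1.61) and Sik1 from 36.9 to 68.6 CPM (0.89), chosen after their values were seen. Exposure to glucocorticoids was a candidate explanation, but the other genes of a glucocorticoid list written for this test had a median log2 fold change of 0.0268 over 14 genes, with an SD of 0.451, and 0 of them were called. The lowest log2 fold change among the prompting genes was 0.82. A difference in the time of day of collection was the other, but the other clock genes had a median of 0.11 over 11 genes, with an SD of 0.282. Both results were negative for these other genes. The prompting genes, picked because they had risen, were left out, so a response limited to such genes is not excluded.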
